A study of Arabidopsis thaliana with 12 samples.

How the data were processed

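RNA was measured by sequencing in 12 libraries of 1-week-old whole Arabidopsis thaliana seedlings, 3 each of wild type mock, cdk8 mock, wild type with ABA and cdk8 with ABA. Per the labels, total RNA was isolated with Trizol, and FastQC, TopHat2 and featureCounts were used with the TAIR10 genome. The deposited table holds the count of fragments assigned to each gene, per the file headers made with featureCounts v1.4.6 in paired-end mode, with exons summed by gene of an Ensembl TAIR10 annotation. Per the file headers no option for strand or for reads mapping to several places was given, so the defaults applied. Counts of overlapping genes on opposite strands are therefore uncertain, among them LEA7, BGLU19, CYP81G1 and DXPS1, and so are those of near-identical copies such as the LHCB1, RBCS, SESA and PDF1.2 families. Library preparation, read length and aligner settings are not given in the sources used here. Groups were taken from the labels and joined to the file's columns by library number. Mock columns are called 0h in the file headers. The library number of cdk8 ABA replicate 3 is 19, apart from the run 1 to 11 of the other libraries.

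Gene symbols and TAIR10 positions came from a reference annotation with 32835 genes, of which 10654 have a symbol; CDK8 is listed there as CDKE;1. Genes were kept by filterByExpr of edgeR over the 4 groups, which left 21151 of 33602 and removed 12451. Scaling was TMM, and quasi-likelihood F tests of edgeR 4.0.16 in R 4.3.3 (limma 3.58.1) were run on 1 design of 4 group means with all 12 libraries. The 5 comparisons were ABA against mock in each genotype, cdk8 against wild type after mock and after ABA, and the difference between the genotypes' ABA responses. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The biological coefficient of variation was 0.126. Between 17675785 and 27415053 fragments were assigned per library, and 3 counts corresponded to 0.109 to 0.17 CPM of these totals, without TMM factors. Folds against a group without counts are lower bounds against a floor of 3 counts over the group, and folds against 1 to 3 counts carry exact 95% intervals. These floors and intervals cover counting error only. P-values measure the spread between samples whose independence the labels do not state.

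Named genes followed a rule fixed before the data were examined, as were the gene lists, the comparisons and most alternatives. The rule took CDK8, RAP2.6 and SnRK2.6, then the 6 called genes with the largest rise and the 6 with the largest fall per comparison. Those had a symbol, at least 5 CPM in a group and, except for the difference of responses, no overlap between the libraries of the 2 groups. It further took up to 2 rising and 2 falling called members of each list. The 26 lists were the 3 target genes, the Mediator kinase module, other Mediator subunits, ABA and dehydration effectors, ABA receptors, clade A PP2C phosphatases, SnRK2 kinases with ABF-type factors, ABA metabolism, the RAP2.6 group of ERF factors, drought and cold factors, cuticular wax and cutin, aquaporins, jasmonate and ethylene, salicylic acid and immune response, phenylpropanoids and flavonoids, mitochondrial stress, glucosinolates, auxin, photosynthesis, root markers, guard cells and stomata, seed storage and oleosins, cell cycle, the circadian clock, hypoxia, and heat shock and touch. The 25 lists with at least 5 members in the fit were tested with camera of limma at a correlation between genes of 0.01, adjusted over the lists by Benjamini-Hochberg, and again with the correlation estimated per list. Member counts were taken at adjusted p over all genes and again over the list alone.

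The size of the ABA response was compared on genes called at least 2-fold in a fit with treatment alone, as the median signed difference of log2 CPM responses. Its two-sided exact permutation test exchanged genotype within treatment in all 400 ways, with a smallest p of 0.005. These exchanges also move the genotype difference itself, so the p does not isolate the difference of responses. Overlaps of called genes are given beside the number expected for independent lists. Tested on simulated data, with 200 of 20725 genes changed, the fit recovered 38.8% of genes changed 1.5-fold, 82.1% at 2-fold and 100% at 4-fold between genotypes after mock, with 6 false calls. For the difference of responses it recovered 6%, 59.7% and 98.5%, with 3 false calls. A simulated response scaled by 0.8 gave a median difference of −0.447 where −0.45 was put in, with permutation p = 0.05. That p was not under 0.05, although −0.45 is larger in size than the −0.124 found in the data. The simulation held no genotype difference after mock, unlike the data.

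Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter or a filter at 1 CPM in 3 libraries, leaving out organelle genes, fitting only the groups compared, a 2-fold limit, adjusted p under 0.01, and each library left out in turn. For the response size they were other gene limits and a prior count of 0.5. Added after the data were seen were thinning to equal depth, leaving out wild-type ABA replicate 3 with cdk8 ABA replicate 2, leaving out cdk8 ABA replicate 3 for the lists, and a replicate block. Raw reads, splicing and variants were not analysed here.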

Results

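Gene-level RNA-seq fragment counts were compared for 1-week-old whole Arabidopsis thaliana seedlings of wild type and the cdk8 mutant, each given mock treatment or 50 µM abscisic acid (ABA) for 3 h. Each of the 4 groups had 3 libraries. Assigned fragments per library were 20531652, 21188494 and 18748275 for wild-type mock, 18906805, 18229473 and 20756476 for cdk8 mock, 18449699, 17675785 and 19326565 for wild-type ABA, and 27415053, 26890432 and 24292745 for cdk8 ABA. Of 33602 genes counted, 21151 were tested. The first principal component separated ABA from mock libraries and held 74.8% of the variance, and the second separated cdk8 from wild type and held 10.4%. ABA replicate 3 of wild type and ABA replicate 2 of cdk8 stood apart from their groups on the fourth component, with scores of −26.7 and −33.7. The same libraries had the highest root and hypoxia list means of their groups, 4.73 and 5.71 on the log2 CPM scale in the wild-type library and 4.26 and 4.66 in the cdk8 library. They were also highest of their groups for the salicylic acid (3.51 and 2.85), wax (5.79 and 4.97), phenylpropanoid (3.56 and 2.96), glucosinolate (5.58 and 5.04) and cell cycle lists (3.32 and 3.54). Salicylic acid means were 2.23 and 2.21 in the other wild-type ABA libraries and 1.81 and 2.19 in the other cdk8 ABA libraries. The 10 most abundant genes took 7.69% to 8.33% of fragments in mock libraries and 5.58% to 6.23% in ABA libraries. Values below are log2 fold changes ± standard error, and adjusted p-values are Benjamini-Hochberg values from edgeR unless a gene list is being tested. Standard errors were taken as the absolute log2 fold change divided by the square root of the F statistic. They are rough for genes near the floor. CPM values are counts scaled to library size multiplied by its TMM factor, given as mean ± SD with n = 3. Genes named for the largest changes between 2 groups had all 3 libraries of a group beyond all 3 of the other, which chance gives for 10% of genes.

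CDK8 measured lower in cdk8, though fragments were still assigned to it in every cdk8 library. Counts summed over a gene do not tell whether the remaining transcript was whole. CDK8 (AT5G63610) measured 21.9, 19.7 and 20.3 CPM in wild-type mock, 5.24, 9.32 and 6.01 CPM in cdk8 mock, 29.2, 29.4 and 26.7 CPM in wild-type ABA, and 10.5, 5.2 and 9.36 CPM in cdk8 ABA. It was lower in cdk8 after mock (−1.60 ± 0.23, adjusted p = 0.000604) and after ABA (−1.77 ± 0.22, adjusted p = 0.000111). ABA gave no call for CDK8 in wild type (0.46 ± 0.21, adjusted p = 0.0693) or in cdk8 (0.29 ± 0.23, adjusted p = 0.297). Without cdk8 ABA replicate 2 both were called, with adjusted p = 0.0139 and 0.0197. Without cdk8 mock replicate 2 CDK8 was called in wild type (0.0422). Over the alternatives its adjusted p in wild type ran from 0.00306 to 0.184, so these were not the only settings that called it. The transcription factor gene RAP2.6 (AT1G43160) went from 2.86 ± 0.614 to 348 ± 118 CPM with ABA in wild type and from 1.05 ± 0.434 to 175 ± 13.6 CPM in cdk8. RAP2.6 was lower in cdk8 after mock (−1.45 ± 0.36, adjusted p = 0.0169) and after ABA (−0.99 ± 0.20, adjusted p = 0.00331), while its ABA response was not called different (0.46 ± 0.41, adjusted p = 0.566). Over the alternatives the adjusted p of RAP2.6 after mock ran from 5.02e-05 to 0.076, and the call was lost with limma-voom (0.076), without wild-type mock replicate 2 (0.068) and without cdk8 mock replicate 1 (0.0676). The ABA kinase gene SnRK2.6 (AT4G33950) was not called different after mock, with 22 ± 0.561 CPM in wild type and 20.5 ± 1.6 CPM in cdk8 (−0.10 ± 0.10, adjusted p = 0.587). ABA raised SnRK2.6 to 90.7 ± 11 CPM in wild type and to 61.7 ± 3.99 CPM in cdk8, and after ABA it was lower in cdk8 (−0.56 ± 0.10, adjusted p = 0.0012). The difference between the SnRK2.6 responses was not called (−0.46 ± 0.14, adjusted p = 0.0764). It was called with DESeq2 (0.0435) and without wild-type ABA replicate 3 (0.0293), and its adjusted p over the alternatives ran from 0.0293 to 0.172.

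**Figure D1:**
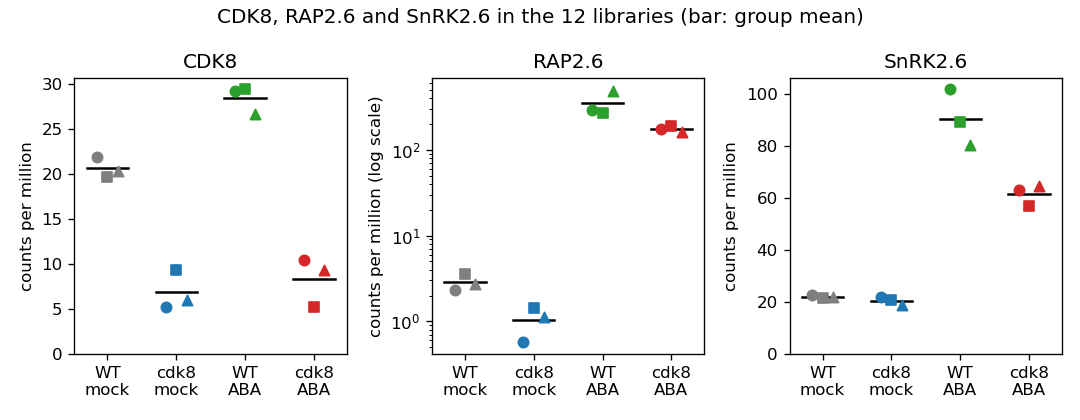
CPM of CDK8, RAP2.6 and SnRK2.6 in each of the 12 libraries. The axis for RAP2.6 is logarithmic.

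What ABA changed in wild-type seedlings was read from ABA against mock. Mock columns are called 0h in the count file, so in both genotypes each difference between ABA and mock can also hold 3 h of time and handling. ABA raised all 9 PP2C phosphatase genes, 25 of 26 dehydration effector genes and 12 of 13 drought transcription factors. It lowered 6 of 10 ABA receptor genes and all 21 photosynthesis genes tested, lists that did not pass with an estimated correlation (adjusted p = 0.122 and 0.0962). Among 21151 genes, 6751 were higher and 6934 lower, of which 2605 and 3510 changed at least 2-fold. With upper-quartile scaling 5484 were higher and 8149 lower, a higher share of 40.2% in place of 49.3%. The largest rises among named genes were HAI3 (AT2G29380; 0.419 to 149 CPM; 8.48 ± 0.26), TSPO (AT2G47770; 8.45 ± 0.24), BGLU24 (AT5G28510; 8.19 ± 0.28), ATHSP22.0 (AT4G10250; 8.06 ± 0.38), LEA7 (AT1G52690; 7.98 ± 0.29) and HSFA6B (AT3G22830; 7.96 ± 0.24), with adjusted p from 8e-12 to 3.04e-09. ATHSP22.0 had only 4 counts over the wild-type mock libraries. The cysteine-rich kinase gene CRK30 (AT4G11460) fell from 13.4 ± 4.2 CPM to no counts, at least 240-fold lower (adjusted p = 2.73e-07). CYP712A2 (AT5G06905) fell from 7.29 ± 0.924 CPM to no counts, at least 129-fold lower (adjusted p = 3.75e-08). UMAMIT36 (AT1G70260) kept 2 counts and was 353-fold lower (exact 95% interval 97.5 to 2920, adjusted p = 5.04e-10). CYP71B36 (AT3G26320) kept 1 count and was 316-fold lower (exact 95% interval 56.4 to 12500, adjusted p = 4.1e-08), and PAP14 (AT2G46880) kept 3 counts and was 143-fold lower (exact 95% interval 48.7 to 697, adjusted p = 1.35e-05). The expansin gene EXPA8 (AT2G40610) went from 149 to 0.975 CPM (−7.26 ± 0.26, adjusted p = 3.73e-11).

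Within the ABA pathway, all 9 clade A PP2C genes rose in wild type, with a list median of 3.6 (list adjusted p = 3.75e-22, adjusted p = 0.0101 with an estimated correlation) and HAI2 at 6.13 ± 0.18. Of 26 dehydration effector genes 25 rose (median 4.03, adjusted p = 5.11e-38, 0.00774 with an estimated correlation), including LEA4-5 at 7.46 ± 0.16 and HB7 at 3.91 ± 0.11. The ABA metabolism list held 10 higher and 3 lower of 13 genes (median 1.48, adjusted p = 0.000249, 0.0431 with an estimated correlation). Named by smallest p in each direction, its breakdown genes CYP707A1 (4.78) and CYP707A3 (2.95) rose and its synthesis genes ABA1 (−0.77) and ABA2 (−0.90) fell. Other synthesis genes were among the 10 higher, so synthesis genes did not fall as a group. Of 10 receptor genes 1 was higher and 6 lower, PYL4 at −3.38 ± 0.16 and PYR1 at −1.62 (median −1.17, adjusted p = 0.0056, but 0.122 with an estimated correlation). SnRK2 kinases and ABF-type factors gave 7 of 8 higher, ABF2 at 1.94 ± 0.08 (median 1.45, adjusted p = 3.92e-06, but 0.114 with an estimated correlation). Drought and cold transcription factors gave 12 of 13 higher, RD26 at 3.97 ± 0.10 and NAC055 at 3.68 (median 2.35, adjusted p = 1.95e-11, 0.0101 with an estimated correlation). The RAP2.6 group of ERF factors gave 5 of 6 higher, ABR1 at 5.95 ± 0.31 (median 3.73, adjusted p = 0.000169, 0.0433 with an estimated correlation). Adjusting over each list alone gave the same counts for these lists.

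Hypoxia, mitochondrial stress and heat lists held mostly higher genes in wild type, and photosynthesis, glucosinolate, cell cycle and phenylpropanoid lists mostly lower genes. Hypoxia and anaerobic genes gave 9 of 10 higher, ADH1 at 5.93 ± 0.17 and SUS1 at 4.54 (median 2.57, adjusted p = 2.07e-05, but 0.161 with an estimated correlation). Mitochondrial stress genes gave 8 higher and 1 lower of 10, or 9 and 1 when adjusted over the list alone, NAC013 at 3.25 and NDA1 at −1.70 (median 1.94, adjusted p = 6.2e-05, but 0.122 with an estimated correlation). Heat shock and touch genes gave 6 higher and 1 lower of 9, or 7 and 1 over the list alone, HSP70 at 3.08 and HSP17.4 at 5.09 (median 2.03, adjusted p = 0.00149, but 0.283 with an estimated correlation). All 21 photosynthesis genes fell, LHCB1.1 at −2.80 and RCA at −2.08 (median −1.50, adjusted p = 2.7e-13, but 0.0962 with an estimated correlation). Glucosinolate genes gave 12 of 17 lower, MYB28 at −2.32 and MYB29 at −2.79 (median −0.70, adjusted p = 0.000746, but 0.426 with an estimated correlation). All 9 cell cycle genes fell, CYCA1;1 at −1.84 and CDKB2;1 at −1.0 (median −0.92, adjusted p = 0.0197, but 0.491 with an estimated correlation). Phenylpropanoid and flavonoid genes gave 2 higher and 10 lower of 17, with TT8 at 1.81 against FLS1 at −2.26 and TT7 at −2.15 (median −0.66, adjusted p = 0.0443, but 0.533 with an estimated correlation).

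The remaining lists were mixed or unchanged after ABA in wild type. Cuticular wax and cutin genes held 8 higher and 3 lower of 12, KCS1 at 2.28 and CER4 at −5.76 (median 1.07, adjusted p = 0.0549). Auxin genes held 4 higher and 11 lower of 20, YUC9 at 2.14 and IAA1 at −2.87 (median −0.98, adjusted p = 0.0549). Jasmonate and ethylene genes held 7 higher and 4 lower of 18, JAZ1 at 2.79 and AOC1 at −1.16 (median 0.45, adjusted p = 0.566). Salicylic acid and immune genes held 6 lower of 15, PAD4 at −1.26 (median −0.38, adjusted p = 0.303), and aquaporins held 4 higher and 8 lower of 18, PIP2;6 at 1.13 and PIP2;8 at −1.44 (median −0.37, adjusted p = 0.435). Root markers held 1 higher and 5 lower of 9, RHD2 at 0.72 and PRP3 at −2.23 (median −0.45, adjusted p = 0.293). Guard cell and stomatal genes held 1 higher and 3 lower of 8, or 1 and 2 over the list alone, GORK at 1.77 and MYB60 at −2.08 (median −0.22, adjusted p = 0.715). None of 5 seed storage and oleosin genes was called (median −1.83, adjusted p = 0.785). In the Mediator kinase module, MED12 (0.51, adjusted p = 0.00826) was higher and CYCC1;2 lower (−0.42, adjusted p = 0.0214), 1 and 1 of 5 (median 0.32, adjusted p = 0.82). The CYCC1;2 call was lost without wild-type mock replicate 3 (0.0523), ABA replicate 1 (0.0864) or ABA replicate 3 (0.0524), with adjusted p from 0.00472 to 0.0864 over the alternatives. Other Mediator subunits gave 3 higher and 2 lower of 9, MED25 at 0.97 and MED8 at −0.39, with a median of −0.11 but a mean of 0.09 and a test pointing up (adjusted p = 0.808). With upper-quartile scaling the median of all genes moved to −0.145 in this comparison from −0.009 with the scaling used here, so small changes are relative to that shift.

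**Figure D2:**
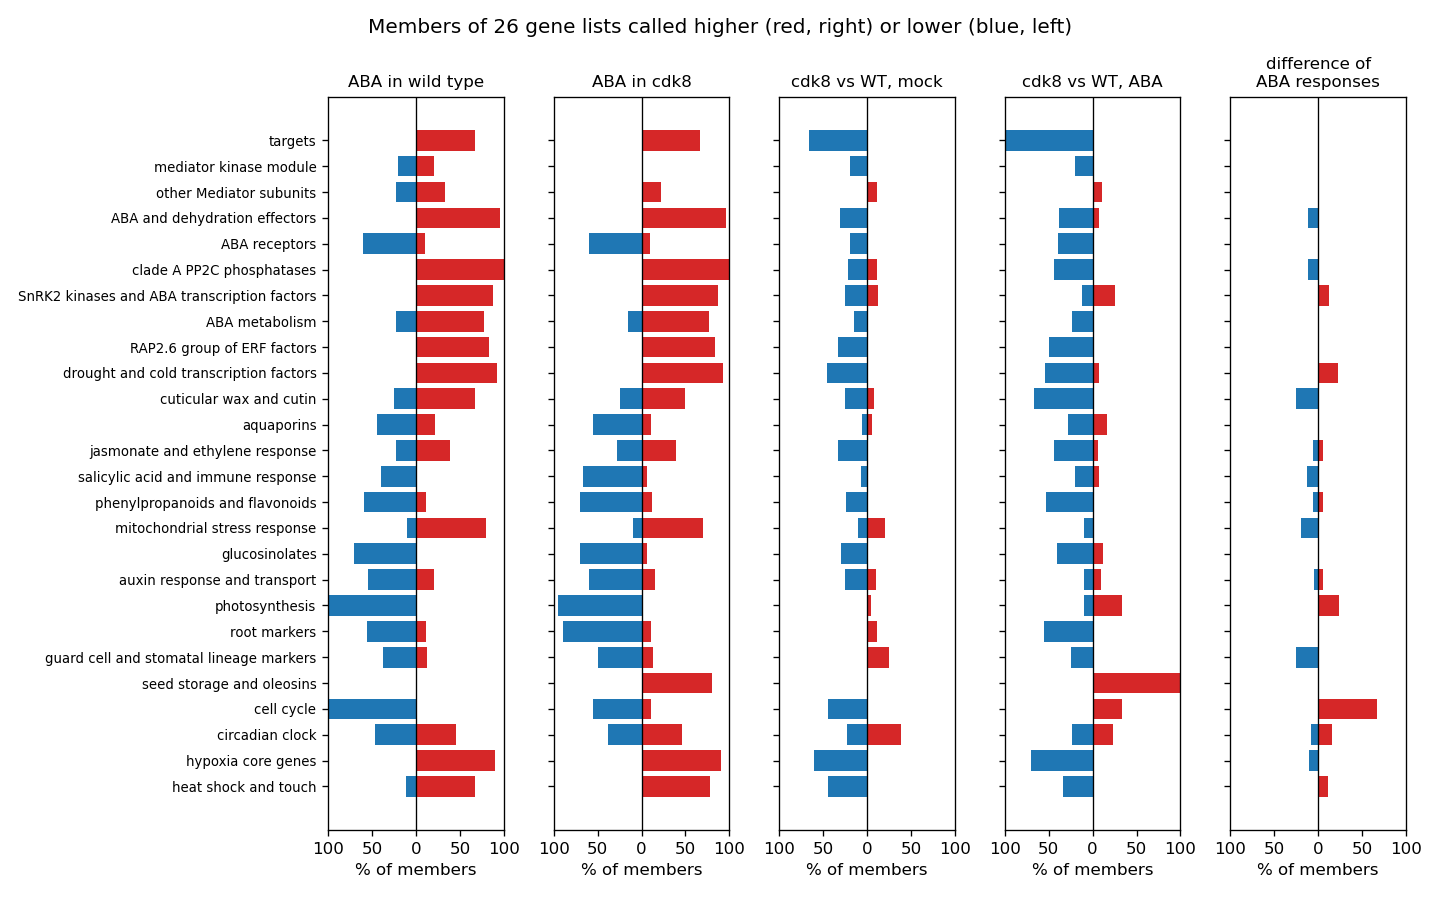
Percentage of the members of each of 26 gene lists called higher (red, to the right) or lower (blue, to the left) in each of the 5 comparisons.

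Clock genes divided by phase after ABA, whatever the genotype. In wild type all 6 evening-phased genes were higher and 5 morning-phased genes lower, among 12 genes of known phase. LUX measured 3.12 and BOA 4.40 in wild type, against LHY at −3.68 and RVE8 at −2.43. The same genes in cdk8 were 2.94, 4.07, −4.19 and −2.83. The whole list of 13 held 6 higher and 6 lower genes in wild type, with a median of −0.17 but a mean of 0.13 and a test pointing up (adjusted p = 0.763). It held 6 higher and 5 lower in cdk8, with a median of 0.00, a mean of 0.10 and a test pointing down (adjusted p = 0.946). A difference of 3 h in clock time between ABA and mock seedlings was not excluded.

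**Figure D3:**
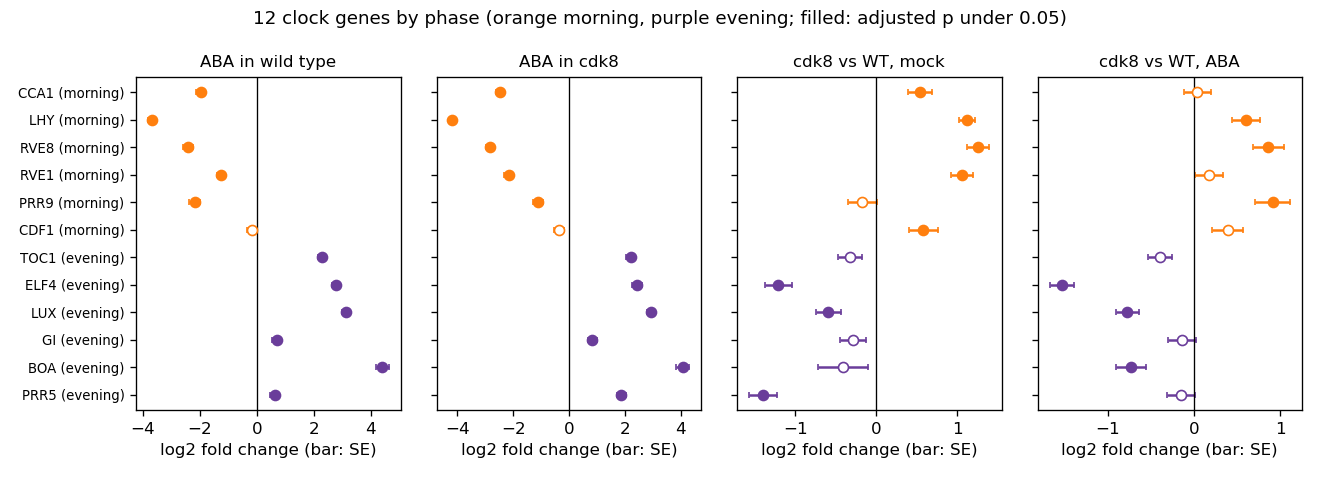
Log2 fold changes with standard errors of 12 clock genes, grouped by phase, after ABA in each genotype and between genotypes after mock and after ABA.

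The cdk8 mutant was compared with ABA and with mock to see which parts of the response remained. Most genes called in wild type were called in the same direction in cdk8. In cdk8 6466 genes were higher and 6430 lower, of which 2433 and 3047 changed at least 2-fold. With upper-quartile scaling 5722 were higher and 7151 lower, a higher share of 44.4% in place of 50.1%. Of the called genes, 5312 were higher in both genotypes where 2063.8 would be shared by independent lists, 5429 were lower in both where 2108 would be, and 71 had opposite signs. Log2 fold changes of the genotypes correlated with r = 0.90. Under the naming rule the largest rises included GASA3 (AT4G09600), which had 2 counts in cdk8 mock and was 708-fold higher (exact 95% interval 196 to 5850, adjusted p = 9.26e-10). They also held HAI3 (9.20 ± 0.29), HSFA6B (8.24 ± 0.26), BGLU24 (7.92 ± 0.27), TSPO (7.92 ± 0.24) and LEA4-5 (AT5G06760; 7.77 ± 0.17), with adjusted p from 2.57e-12 to 3.57e-11. EXPA8 fell again (−7.84 ± 0.26, adjusted p = 2.63e-11), with EXT13 (AT5G35190; −6.32 ± 0.42, adjusted p = 1.34e-08), CYP712A2 (−5.95 ± 0.40, adjusted p = 7.17e-08), CYP82C4 (AT4G31940; −6.80 ± 0.71, adjusted p = 1.45e-06) and the terpene synthase gene TPS04 (AT1G61120; −6.71 ± 1.47, adjusted p = 0.00124). CYP71B36 kept 3 counts and was 158-fold lower (exact 95% interval 53.5 to 768, adjusted p = 2.29e-08).

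Gene lists of the ABA pathway were tested in cdk8 as in wild type. Dehydration effectors gave 25 of 26 higher (median 4.00, adjusted p = 4.15e-41, 0.00371 with an estimated correlation), ERD10 at 3.98. PP2C genes gave 9 of 9 higher, HAI2 at 5.52 (median 3.20, adjusted p = 2.42e-20, 0.0113 with an estimated correlation). Kinases and ABF factors gave 7 of 8 higher, or 8 over the list alone, ABF2 at 2.0 and ABF1 at 1.81 (median 1.70, adjusted p = 6.76e-09, 0.0441 with an estimated correlation). ABA metabolism gave 10 higher and 2 lower of 13, CYP707A1 at 4.65 and CYP707A3 at 3.43 (median 1.29, adjusted p = 0.000104, 0.0268 with an estimated correlation). The RAP2.6 group gave 5 of 6 higher, ABR1 at 5.92 (median 3.16, adjusted p = 0.000104, 0.0196 with an estimated correlation), and drought factors 12 of 13, RD26 at 3.76 and ZAT6 at 3.33 (median 3.33, adjusted p = 1.35e-14, 0.00371 with an estimated correlation). Receptors gave 1 higher and 6 lower of 10, PYL4 at −3.62 (median −1.22, adjusted p = 0.00286, but 0.124 with an estimated correlation). Photosynthesis genes gave 20 of 21 lower, RCA at −2.33 (median −1.35, adjusted p = 1.36e-11, but 0.101 with an estimated correlation). Hypoxia genes gave 9 of 10 higher, or 9 and 1 lower over the list alone, ADH1 at 6.05 (median 2.85, adjusted p = 1.39e-05, but 0.145 with an estimated correlation), and heat and touch genes 7 of 9, HSP17.4 at 5.24 (median 2.6, adjusted p = 0.000156, but 0.159 with an estimated correlation).

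Growth, defence and seed lists were tested in cdk8 as well. Cell cycle genes did not pass as a list, with 1 higher and 5 lower of 9, or 2 and 5 over the list alone, MCM2 at −0.83 and MCM5 at −0.81 (median −0.22, adjusted p = 0.487). Root markers fell, 1 higher and 8 lower of 9, PRP3 at −3.47 and LRX1 at −2.57 (median −1.06, adjusted p = 0.0274, but 0.441 with an estimated correlation). Auxin genes gave 3 higher and 12 lower of 20, IAA1 at −3.20 and PIN3 at −1.53 (median −0.65, adjusted p = 0.0263, but 0.182 with an estimated correlation). Phenylpropanoid genes gave 2 higher and 12 lower of 17, or 13 lower over the list alone, TT7 at −2.12 (median −0.99, adjusted p = 0.00879, but 0.402 with an estimated correlation). Glucosinolate genes gave 1 higher and 12 lower of 17, MYB28 at −2.51 (median −0.73, adjusted p = 0.000787, but 0.402 with an estimated correlation), and mitochondrial stress genes 7 higher and 1 lower of 10, UPOX at 3.09 (median 1.76, adjusted p = 0.000156, but 0.145 with an estimated correlation). Salicylic acid genes gave 1 higher and 10 lower of 15, PAD4 at −1.60 and EDS1 at −1.10 (median −1.36, adjusted p = 0.0501). Seed genes gave 4 of 5 higher, OLEO2 at 2.82 with 11.8, 0.824 and 6.46 CPM in the cdk8 ABA libraries (median 2.53, adjusted p = 0.487). Wax genes gave 6 higher and 3 lower of 12, with a median of 0.23 but a mean of −0.16 (adjusted p = 0.603). Jasmonate genes (7 higher, 5 lower of 18, median 0.34, the same with 1 member at its bound, adjusted p = 0.446), aquaporins (2 higher, 10 lower of 18, median −0.65, adjusted p = 0.136) and guard cell genes (1 higher, 4 lower of 8, median −0.74, adjusted p = 0.183) were mixed. No Mediator kinase module gene was called (median 0.23, adjusted p = 0.946), and other Mediator subunits gave 2 of 9 higher, MED25 at 0.77, with a median of −0.01 but a mean of 0.10 (adjusted p = 0.756).

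How cdk8 differed from wild type without ABA was read from the mock libraries. Iron uptake genes among those named were higher in cdk8. Genes called lower were found in the hypoxia (6 of 10), heat and touch (4 of 9), jasmonate (6 of 18), drought factor (6 of 13) and glucosinolate (5 of 17) lists. None of these lists passed with an estimated correlation (adjusted p = 0.283, 0.301, 0.282, 0.0886 and 0.58). In all, 1089 genes were higher and 1692 lower, of which 202 and 592 differed at least 2-fold. The ferric reductase gene FRO2 (AT1G01580) measured 2.53 CPM in wild type and 45.6 CPM in cdk8 (4.16 ± 0.24, adjusted p = 7.07e-07), with BHLH100 (AT2G41240; 4.13 ± 0.63, adjusted p = 0.00147), bHLH38 (AT3G56970; 3.73 ± 0.42, adjusted p = 0.000104), bHLH39 (AT3G56980; 3.37 ± 0.40, adjusted p = 0.000146) and the iron transporter gene IRT1 (AT4G19690; 2.90 ± 0.35, adjusted p = 0.000186). GLP9 (AT4G14630) was also higher (3.44 ± 0.38, adjusted p = 0.000103). The acyltransferase gene AACT1 (AT5G61160) was lower, 6.9 CPM in wild type and 0.0722 CPM in cdk8 (−6.53 ± 0.57, adjusted p = 3.81e-05). DIN11 (AT3G49620; −5.21 ± 0.90, adjusted p = 0.00207), BAM5 (AT4G15210; −3.87 ± 0.60, adjusted p = 0.00102), GAD4 (AT2G02010; −3.53 ± 0.45, adjusted p = 0.000249) and CWINV5 (AT3G13784; −3.33 ± 0.35, adjusted p = 5.19e-05) were lower too. ABCG40 (AT1G15520) was lower (−3.28 ± 0.60, adjusted p = 0.0029), with 36.5, 4.66 and 40.8 CPM in the wild-type mock libraries. The defensin gene PDF1.2 (AT5G44420) measured 1.78, 3.8 and 1.69 CPM in wild-type mock and no counts in cdk8 mock, at least 47.7-fold lower (adjusted p = 0.00162). Calls were lost for DIN11 (0.1) and ABCG40 (0.0749) with limma-voom and for BHLH100 (0.051) with DESeq2, where the other alternatives reached adjusted p of 3.19e-07, 1.64e-05 and 8.84e-06. Without wild-type mock replicate 1, 2 or 3 or cdk8 mock replicate 1 or 2, the genes called numbered 1761, 1759, 1608, 1782 and 1486 in place of 2781, and they numbered 4383 without both ABA libraries that stood apart. A fit of the mock groups only gave 4472.

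At a correlation of 0.01, 9 lists were lower in cdk8 after mock, and none passed with an estimated correlation. Hypoxia genes gave 6 of 10 lower, or 7 over the list alone, SUS4 at −1.61 and ADH1 at −1.06 (median −1.21, adjusted p = 1.99e-06, but 0.283 with an estimated correlation). Drought factors gave 6 of 13 lower, or 8 over the list alone, CBF1 at −2.73 ± 0.38 and ZAT6 at −1.50 ± 0.16 (median −0.66, adjusted p = 1.96e-06, but 0.0886 with an estimated correlation). Heat and touch genes gave 4 of 9 lower, or 6 over the list alone, TCH3 at −1.84 and HSP18.2 at −1.75 (median −0.77, adjusted p = 0.000207, but 0.301 with an estimated correlation). Jasmonate genes gave 6 of 18 lower, or 8 over the list alone, VSP2 at −1.78 ± 0.28 (median −0.39, the same with 3 members without counts at their bound, adjusted p = 0.000207, but 0.282 with an estimated correlation). Glucosinolate genes gave 5 of 17 lower, or 1 higher and 7 lower over the list alone, MYB51 at −1.85 ± 0.14 (median −0.29, adjusted p = 0.000421, but 0.58 with an estimated correlation). Dehydration effectors gave 8 of 26 lower, or 9 over the list alone, LTP3 at −1.69 ± 0.26 (median −0.30, adjusted p = 0.00337, but 0.58 with an estimated correlation). Phenylpropanoid genes gave 4 of 17 lower, TT8 at −1.63 (median −0.39, adjusted p = 0.0183, but 0.618 with an estimated correlation). The RAP2.6 group gave 2 of 6 lower (median −0.88, adjusted p = 0.0478, but 0.295 with an estimated correlation), and cell cycle genes 4 of 9, KNOLLE at −0.89 (median −0.20, adjusted p = 0.0478, but 0.66 with an estimated correlation). Without cdk8 ABA replicate 3 the RAP2.6 group did not pass (0.0528). Without both ABA libraries that stood apart neither the RAP2.6 group (0.053) nor the cell cycle list (0.0643) passed.

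The other lists did not pass after mock, though single members differed. Among PP2C genes HAB1 was higher (0.51), while ABI1 (−0.51) and HAI2 (−1.32) were lower, and 1 and 3 of 9 were called over the list alone (median −0.05, adjusted p = 0.483). Receptors gave 2 of 10 lower, PYL6 at −1.49 and PYL5 at −0.67 (median −0.14, adjusted p = 0.201). ABA metabolism gave 2 of 13 lower, or 3 over the list alone, CYP707A3 at −1.18 (median −0.10, adjusted p = 0.365), and kinases and ABF factors 1 higher and 2 lower of 8, ABF1 at −0.57 (median −0.10, adjusted p = 0.226). In the Mediator kinase module CDK8 was the only call over all genes, with 3 higher and 1 lower of 5 over the list alone, a median of 0.34 and a mean of −0.08 (adjusted p = 0.771). Salicylic acid genes gave 1 of 15 lower, PAD3 at −2.36 (median 0.33, adjusted p = 0.365), and auxin genes 2 higher and 5 lower of 20, or 3 and 5 over the list alone, IAA14 at 0.79 and IAA19 at −0.89 (median −0.13, adjusted p = 0.483). Clock genes gave 5 higher and 3 lower of 13, LHY at 1.12 and PRR5 at −1.40, with a median of −0.17 and a mean of 0.01 (adjusted p = 0.437). Wax genes gave 1 higher and 3 lower of 12, or 2 and 3 over the list alone, CER3 at 0.71 and CYP86A4 at −1.59 (median −0.21, adjusted p = 0.325). Guard cell genes gave 2 of 8 higher, KAT1 at 1.04 and FAMA at 0.57 (median 0.06, adjusted p = 0.202). Photosynthesis genes (1 of 21 higher, none over the list alone, median −0.10, adjusted p = 0.828), aquaporins (1 higher and 1 lower of 18, median −0.06, test pointing up, adjusted p = 0.866), mitochondrial stress genes (2 higher and 1 lower of 10, 2 and 3 over the list alone, median −0.16, adjusted p = 0.815), root markers (SCR at 0.53 of 9, median −0.24, adjusted p = 0.815), other Mediator subunits (1 of 9 higher, 2 over the list alone, median 0.15, adjusted p = 0.241) and seed genes (none of 5, median 1.27, adjusted p = 0.18) did not pass.

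How cdk8 differed from wild type under ABA was read from the ABA libraries. Genes called lower in cdk8 were found in the PP2C (4 of 9), wax (8 of 12), hypoxia (7 of 10) and jasmonate (8 of 18, with 1 higher) lists. All 5 seed storage genes were called higher, with list means of 3.28, −0.47 and 2.02 on the log2 CPM scale over the cdk8 ABA libraries. None of these lists passed with an estimated correlation (adjusted p = 0.337, 0.307, 0.307 and 0.337, and 0.387 for seed genes). In all, 2244 genes were higher and 2755 lower, of which 363 and 792 differed at least 2-fold. With upper-quartile scaling the majority turned, with 2865 higher and 2417 lower, a higher share of 54.2% in place of 44.9%. The genotype differences after mock and after ABA share no libraries, and 412 genes were higher in both where 115.5 would be shared by independent lists, 832 lower in both where 220.4 would be, and 99 opposite. Higher in cdk8 by most among genes with at least 5 CPM in a group and no overlap of libraries were OLEO2 (AT5G40420; 5.34 ± 0.97, adjusted p = 0.00162), CRC (AT4G28520; 5.22 ± 1.22, adjusted p = 0.00781), PER1 (AT1G48130; 4.44 ± 0.88, adjusted p = 0.00292) and BGLU19 (AT3G21370; 3.82 ± 1.02, adjusted p = 0.0155), with NAS2 (AT5G56080; 3.67 ± 0.44, adjusted p = 7.8e-05) and GLP9 (2.07 ± 0.37, adjusted p = 0.00152). OLEO2 measured 11.8, 0.824 and 6.46 CPM in the cdk8 ABA libraries, and CRC 16.4, 0.86 and 4.34. PER1 measured 7.39, 1.15 and 7.87 CPM there and BGLU19 8.52, 2.15 and 13, so all of these were lowest in replicate 2. Lower in cdk8 were DIN11 (−5.86 ± 0.60, adjusted p = 2.39e-05), NATA1 (AT2G39030; −4.66 ± 0.70, adjusted p = 0.000433), CYP81G1 (AT5G67310; −4.66 ± 0.53, adjusted p = 5.05e-05), CWINV5 (−3.86 ± 0.28, adjusted p = 1.73e-06), DIC3 (AT5G09470; −3.27 ± 0.32, adjusted p = 1.89e-05) and RLP33 (AT3G05660; −3.22 ± 0.41, adjusted p = 0.000141). PDF1.2 was lower as after mock (−5.61 ± 0.75, adjusted p = 0.000362). With limma-voom the calls were lost for OLEO2 (0.103), CRC (0.138), PER1 (0.0546) and BGLU19 (0.0673), where the lowest adjusted p over the alternatives were 1.81e-05, 0.000897, 0.000176 and 0.00483, and without cdk8 ABA replicate 3 the call was lost for BGLU19 (0.0524). Without cdk8 ABA replicate 1 the genes called numbered 3099 in place of 4999. A fit of the ABA groups only gave 2931, fewer than the 4472 of a fit of the mock groups only.

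PP2C, wax, hypoxia, effector, drought factor and RAP2.6 group lists were lower in cdk8 under ABA at a correlation of 0.01, and none passed with an estimated correlation. PP2C genes gave 4 of 9 lower, or 5 over the list alone, HAI2 at −1.92 ± 0.13 and ABI1 at −0.90 ± 0.09 (median −0.32, adjusted p = 0.000182, but 0.337 with an estimated correlation). Wax and cutin genes gave 8 of 12 lower, CER1 at −0.97 and WSD1 at −3.17 (median −0.63, adjusted p = 1.12e-05, but 0.307 with an estimated correlation). Hypoxia genes gave 7 of 10 lower, or 9 over the list alone, SUS1 at −1.80 and ADH1 at −0.94 (median −1.03, adjusted p = 6.24e-06, but 0.307 with an estimated correlation). Dehydration effectors gave 2 higher and 10 lower of 26, or 4 and 16 over the list alone, EM1 at 1.37 and P5CS1 at 0.90 against LTP3 at −1.97 and LTP4 at −2.25 (median −0.34, adjusted p = 0.00193, but 0.494 with an estimated correlation). Drought factors gave 1 higher and 7 lower of 13, or 1 and 8 over the list alone, RD26 at −0.68 and ZAT6 at −0.80 (median −0.68, adjusted p = 0.0048, but 0.307 with an estimated correlation). The RAP2.6 group gave 3 of 6 lower, with RAP2.6L at −1.27 and ABR1 at −1.28 beside RAP2.6 (median −0.86, adjusted p = 0.0207, but 0.307 with an estimated correlation).

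Jasmonate, phenylpropanoid, root, glucosinolate and heat lists were lower as well at a correlation of 0.01, and none passed with an estimated correlation. Jasmonate genes gave 1 higher and 8 lower of 18, or 3 and 9 over the list alone, OPR3 at 0.63 and LOX2 at −1.25 (median −0.60, the same with 2 members at their bound, adjusted p = 0.0041, but 0.337 with an estimated correlation). Phenylpropanoid genes gave 9 of 17 lower, UF3GT at −2.26 and C4H at −0.72 (median −0.51, adjusted p = 0.00243, but 0.494 with an estimated correlation). Root markers gave 5 of 9 lower, or 1 higher and 8 lower over the list alone, LRX1 at −1.27 and PRP3 at −1.17 (median −0.75, adjusted p = 0.00751, but 0.494 with an estimated correlation). Glucosinolate genes gave 2 higher and 7 lower of 17, MYB51 at −1.28 and CYP79B2 at −1.17, with adjusted p = 0.0207 (0.56 with an estimated correlation, 0.0557 without cdk8 ABA replicate 3) at a median of −0.19. Heat and touch genes gave 3 of 9 lower, or 4 over the list alone, HSP18.2 at −2.47 and TCH3 at −1.99 (median −0.20, adjusted p = 0.0291, but 0.55 with an estimated correlation). Without both ABA libraries that stood apart the glucosinolate (0.103) and heat (0.0518) lists did not pass.

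Tests of the seed, cell cycle and photosynthesis lists pointed up in cdk8 under ABA, and none passed with an estimated correlation. All 5 seed genes were higher, OLEO1 at 4.11 (median 5.22, the same with 1 member at its bound, adjusted p = 0.00193, but 0.387 with an estimated correlation), and their mean per library is shown beside root and hypoxia lists. Cell cycle genes gave 3 of 9 higher, or 5 over the list alone, CDKB2;1 at 0.58 (median 0.50, adjusted p = 0.0227, but 0.56 with an estimated correlation). Photosynthesis genes gave 7 higher and 2 lower of 21, LHCB1.1 at 1.26 and LHCB2.2 at 1.42 against RBCS2B at −0.84 (adjusted p = 0.0374, but 0.56 with an estimated correlation and 0.0967 without cdk8 ABA replicate 3). The photosynthesis median was −0.01 while its mean was 0.19 and its test pointed up, and the median was 0.03 with upper-quartile scaling. Receptors gave 4 of 10 lower, PYR1 at −0.40 (median −0.39, adjusted p = 0.274), and ABA metabolism 3 of 13, or 2 higher and 4 lower over the list alone, CYP707A3 at −0.70 (median −0.17, adjusted p = 0.388). Kinases and ABF factors gave 2 higher and 1 lower of 8, ABF4 at 0.45, ABF1 at 0.33 and SnRK2.6 lower (median 0.09, adjusted p = 0.478). Salicylic acid genes gave 1 higher and 3 lower of 15, PAD3 at −2.09 (median −0.34, adjusted p = 0.337). Auxin genes gave 2 higher and 2 lower of 20, IAA14 at 1.06 and GH3.3 at −2.73 (median −0.29, adjusted p = 0.337). Aquaporins gave 3 higher and 5 lower of 18, or 3 and 6 over the list alone, TIP2;3 at −2.16 (median −0.25, adjusted p = 0.225). Clock genes gave 3 higher and 3 lower of 13, or 4 and 4 over the list alone, RVE8 at 0.86 and ELF4 at −1.53, with a median of 0.04 but a mean of −0.02 (adjusted p = 0.592). Guard cell genes (2 of 8 lower, median −0.18, adjusted p = 0.478), mitochondrial stress genes (1 of 10 lower, median −0.27, adjusted p = 0.174) and other Mediator subunits (MED5A at 0.54 of 9, median 0.08, adjusted p = 0.225) did not pass. In the Mediator kinase module CDK8 was the only call, with 2 higher and 1 lower of 5 over the list alone, a median of 0.21 and a mean of −0.14 (adjusted p = 0.953).

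**Figure D4:**
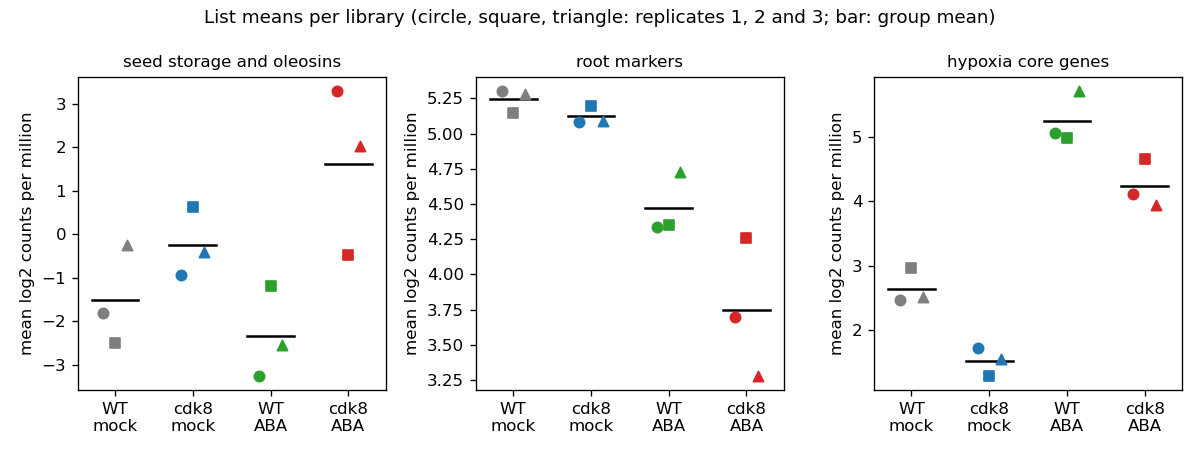
Mean log2 CPM of the seed, root and hypoxia lists in each library. Circles, squares and triangles are replicates 1, 2 and 3 of a group.

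Whether cdk8 answered ABA differently was read from the difference between the genotypes' ABA responses. CBF1, CBF2 and 6 of 9 cell cycle genes responded more positively in cdk8, and 3 of 12 wax genes, FMO1 and TPS04 more negatively. With an estimated correlation neither the cell cycle nor the wax list passed (adjusted p = 0.656 for both). The response differed for 1103 genes, 501 more positive and 602 more negative in cdk8, of which 235 and 213 differed at least 2-fold. The more positive share was 45.4%, and it was 58.5% with upper-quartile scaling. Named genes with the largest positive differences were ABCG40 (3.22 ± 0.77, adjusted p = 0.0298), GAD4 (2.33 ± 0.56, adjusted p = 0.0305), CBF2 (AT4G25470; 2.02 ± 0.29, adjusted p = 0.00215), PS2 (AT1G73010; 1.97 ± 0.44, adjusted p = 0.0221), CBF1 (AT4G25490; 1.93 ± 0.44, adjusted p = 0.0239) and AHP4 (AT3G16360; 1.83 ± 0.33, adjusted p = 0.0073). Each was lower in every cdk8 mock library than in every wild-type mock library. After ABA only CBF2 was higher in every cdk8 library, with 18.7, 15.2 and 21.2 CPM against 14.6, 10.7 and 10.5 in wild type. CBF1 was still lower after ABA, with 5.15, 3.94 and 4.78 CPM in cdk8 against 7.01, 7.27 and 9.78 in wild type, and so was GAD4. Those with the largest negative differences were TPS04 (−8.23 ± 1.93, adjusted p = 0.0271), DXPS1 (AT3G21500; −5.29 ± 1.04, adjusted p = 0.012), ELI3-2 (AT4G37990; −5.17 ± 1.29, adjusted p = 0.035), NATA1 (−4.24 ± 1.01, adjusted p = 0.0291), JRG21 (AT3G55970; −4.13 ± 0.81, adjusted p = 0.0118) and CSLG2 (AT4G24000; −3.96 ± 0.81, adjusted p = 0.0137). TPS04 measured 4.87, 0.499 and 11.8 CPM in cdk8 mock and 0, 0.143 and 0 CPM in cdk8 ABA. The calls for CBF2, AHP4, DXPS1, JRG21 and CSLG2 were made whichever library was left out, though DXPS1 and JRG21 lost theirs with limma-voom. The other 7 were lost without single libraries, with adjusted p up to 0.0828 for ABCG40, 0.0878 for GAD4, 0.059 for PS2, 0.0704 for CBF1, 0.152 for TPS04, 0.106 for ELI3-2 and 0.0962 for NATA1. Without wild-type mock replicate 1, 2 or 3, cdk8 mock replicate 1 or 2, or cdk8 ABA replicate 1, the genes called numbered 678, 688, 586, 540, 629 and 545 in place of 1103, and they numbered 2063 without both ABA libraries that stood apart. DESeq2 called 1714.

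Cell cycle genes gave 6 of 9 more positive responses in cdk8, CDKB2;1 at 0.78 and AUR1 at 0.96 (median 0.78, adjusted p = 5.22e-05, but 0.656 with an estimated correlation). Wax genes gave 3 of 12 more negative, or 5 over the list alone, CER3 at −1.20 and CER1 at −0.86 (median −0.51, adjusted p = 0.000595, but 0.656 with an estimated correlation). Photosynthesis genes gave 5 of 21 more positive, or 5 and 3 more negative over the list alone, LHCB1.1 at 1.24 and LHCB2.2 at 1.22 (median 0.16, adjusted p = 0.0436, but 0.893 with an estimated correlation and 0.122 without cdk8 ABA replicate 3). PP2C genes gave 1 of 9 more negative, HAB1 at −0.83, or 2 over the list alone (median −0.39, adjusted p = 0.0436, but 0.783 with an estimated correlation and 0.0827 without cdk8 ABA replicate 3). Root markers gave no call, or 1 more negative over the list alone (median −0.52, adjusted p = 0.0228, but 0.783 with an estimated correlation and 0.108 without cdk8 ABA replicate 3). Dehydration effectors gave 3 of 26 more negative, or 1 and 4 over the list alone, RD20 at −1.76 and HB7 at −0.70 (median −0.13, adjusted p = 0.612). Drought factors gave 3 of 13 more positive, or 4 and 1 over the list alone (median 0.63, adjusted p = 0.0808), and kinases and ABF factors 1 of 8, ABF1 at 0.89, or 2 and 1 over the list alone (median 0.25, adjusted p = 0.0735). Salicylic acid genes gave 2 of 15 more negative, or 3 over the list alone, FMO1 at −3.58 (median −0.34, adjusted p = 0.0777). Guard cell genes gave 2 of 8 more negative, KAT1 at −1.53 (median −0.17, adjusted p = 0.0735). Jasmonate genes gave 1 and 1 of 18, or 2 and 1 over the list alone, LOX2 at −1.19 (median 0.14, −0.01 with DESeq2, adjusted p = 0.899), and clock genes 2 and 1 of 13, PRR5 at 1.25 (median −0.19, adjusted p = 0.93).

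Remaining lists did not pass the test of a difference in their ABA response. Auxin genes gave 1 and 1 of 20, or 3 and 1 over the list alone, IAA19 at 1.22 (median −0.30, adjusted p = 0.849). Phenylpropanoid genes gave 1 and 1 of 17, or 1 and 2 over the list alone (median −0.27, adjusted p = 0.43). Hypoxia genes gave 1 of 10 more negative, SUS1 at −1.38 (median 0.15, test pointing down, adjusted p = 0.954), heat and touch genes 1 of 9 more positive (median 0.11, adjusted p = 0.285), and mitochondrial stress genes 2 of 10 more negative (median −0.04, 0.02 with upper-quartile scaling, adjusted p = 0.292). None was called over all genes among receptors (median 0.08, test pointing down, adjusted p = 0.95), ABA metabolism (median 0.13, adjusted p = 0.93), the RAP2.6 group (median 0.21, adjusted p = 0.954), the Mediator kinase module (median −0.07, adjusted p = 0.93) or seed genes (median 4.44, adjusted p = 0.057, but 0.0135 without both ABA libraries that stood apart). The same held for aquaporins, with 1 more positive and 3 more negative of 18 over the list alone (median −0.23, adjusted p = 0.178), for glucosinolate genes (median −0.04, mean 0.07, median 0.02 with upper-quartile scaling, adjusted p = 0.809) and for other Mediator subunits (median −0.05, mean 0.01, median 0.02 with upper-quartile scaling, adjusted p = 0.954).

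Whether cdk8 dampened the whole ABA response was asked of 5670 genes that changed at least 2-fold with ABA in a fit blind to genotype. Response sizes of these ABA-regulated genes had a median of 1.653 in wild type and 1.529 in cdk8. The median difference was −0.124, so the fold change in cdk8 was at the median 0.918 times that in wild type for the same gene. Of these genes 60.4% responded less in cdk8. A two-sided exact permutation test over 400 reassignments of genotype gave p = 0.185 where the smallest p allowed was 0.005. Reassignments that exchange genotype in only 1 treatment measure the genotype difference in place of the difference of responses. Neither this p nor those below can therefore decide on dampening. The difference was −0.08 without wild-type ABA replicate 1 and −0.072 with no fold limit, where rising genes gave −0.058. With the 2-fold limit the 2462 rising genes differed by −0.131 (permutation p = 0.39) and the 3208 falling genes by −0.12 (permutation p = 0.035). Dampening was not called over all ABA-regulated genes, and the permutation test for falling genes did not pass without wild-type mock replicate 1 (−0.104, p = 0.115), 2 (−0.126, p = 0.05) or 3 (−0.095, p = 0.15), wild-type ABA replicate 1 (−0.077, p = 0.085) or cdk8 ABA replicate 1 (−0.109, p = 0.055).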

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

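The tests on seed storage genes and on clock genes were chosen after the result was seen, and so were thinning to equal depth and leaving out both ABA libraries that stood apart, which were added once the data had been seen.

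The ABA response of 12 named genes differed between cdk8 and wild type by the test of that difference. Positive differences were 3.22 for ABCG40, 2.33 for GAD4, 2.02 for CBF2, 1.97 for PS2, 1.93 for CBF1 and 1.83 for AHP4. These genes started lower in cdk8 mock, and after ABA only CBF2 was higher in every cdk8 library than in wild type. Negative differences were −8.23 for TPS04, −5.29 for DXPS1, −5.17 for ELI3-2, −4.24 for NATA1, −4.13 for JRG21 and −3.96 for CSLG2. In wild-type ABA replicate 3, which stood apart, TPS04 measured 4.55 CPM against 0.232 and 0.355 in the other replicates, ELI3-2 49.2 CPM against 10.1 and 9.28, JRG21 86.6 against 30.6 and 26.6, DXPS1 26 against 8.63 and 6.86, and NATA1 22.7 against 9.67 and 8.52. DXPS1 lost its call with limma-voom (adjusted p = 0.117, with a lowest value of 0.000312 over its alternatives), as did JRG21 (0.0721, lowest 0.000792).

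Single libraries ended 7 of these calls. ABCG40 (adjusted p from 0.000473 to 0.172 over its alternatives) was lost without wild-type mock replicates 1 (0.0703) or 3 (0.0751), cdk8 mock replicates 1 (0.0739), 2 (0.0828) or 3 (0.0548), wild-type ABA replicate 2 (0.062) or cdk8 ABA replicate 1 (0.061), and stood at 0.05 without wild-type ABA replicate 1. GAD4 (0.00494 to 0.141) was lost without wild-type mock replicates 1 (0.0585) or 3 (0.0615), cdk8 mock replicates 1 (0.0782), 2 (0.0878) or 3 (0.0611), wild-type ABA replicates 1 (0.0579) or 2 (0.0581), or cdk8 ABA replicate 3 (0.056). PS2 (0.00614 to 0.059) was lost without cdk8 mock replicates 1 (0.059) or 3 (0.0544) or wild-type ABA replicate 2 (0.0504). CBF1 (0.00838 to 0.0704) was lost without wild-type mock replicate 1 (0.0556), cdk8 mock replicates 1 (0.0528) or 2 (0.0704), or cdk8 ABA replicate 1 (0.055). TPS04 (0.00501 to 0.165) was lost without wild-type mock replicates 2 (0.0614) or 3 (0.0649), cdk8 mock replicates 1 (0.0524) or 3 (0.0594), wild-type ABA replicate 3 (0.152), or cdk8 ABA replicates 1 (0.0763) or 3 (0.058). ELI3-2 (0.0154 to 0.286) was lost without wild-type mock replicates 1 (0.0764), 2 (0.0926) or 3 (0.0756), cdk8 mock replicates 1 (0.106) or 3 (0.0727), or cdk8 ABA replicates 1 (0.0805) or 3 (0.0587). NATA1 (0.00433 to 0.0962) was lost without wild-type mock replicate 3 (0.065), cdk8 mock replicates 1 (0.0711) or 3 (0.0962), or cdk8 ABA replicate 1 (0.0695).

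Other ways of dividing the libraries were counted for each comparison. For the comparisons of 3 against 3 libraries, the real split was 1 of 10, too few for a share under 0.05. It gave 13685 genes for ABA in wild type, 12896 for ABA in cdk8, 2781 for genotype after mock and 4999 for genotype after ABA. The highest of the others gave 0, 0, 0 and 1. Each of those others mixed both groups, which adds their difference to the spread, so low counts were set in advance. These splits therefore decide nothing about chance. For the difference of responses, 1 of 100 reassignments of genotype within treatment gave as many as the real 1103 genes, which is the real assignment itself, and the highest other gave 903. This count decides nothing about chance. Reassignments that mixed genotypes within both treatments added the genotype difference to the spread between libraries, and all 84 of these gave 0 genes. The 15 others that kept the real grouping in 1 treatment gave up to 903, and that one put wild-type ABA replicates 2 and 3 with cdk8 ABA replicate 2.

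The ABA response was smaller in cdk8 by a median of −0.124, without passing its permutation test (p = 0.185). Deeper sequencing of the cdk8 ABA libraries was argued against, since the value was −0.123 with all libraries thinned to equal depth. The 2 ABA libraries that stand apart with higher root and hypoxia genes were argued against as its source too, since the value was −0.142 without them. A weaker response in the mutant may remain, and chance was not excluded either. The permutation p of 0.185 cannot decide between them, since its reassignments also hold the genotype difference.

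All 5 seed storage and oleosin genes tested were called higher in cdk8 after ABA, and their list did not pass with an estimated correlation (adjusted p = 0.387). Their list mean was 3.28, −0.47 and 2.02 on the log2 CPM scale over the cdk8 ABA libraries, a range of 3.75. Seed or embryo material in single libraries would give such a range. List means also varied in wild type, with −1.81, −2.5 and −0.24 after mock and −3.26, −1.19 and −2.56 after ABA. The range therefore cannot tell seed material from other variation between libraries. CRA1 measured 23, 0.537 and 15.5 CPM over the cdk8 ABA libraries, and 0.528, 0.143 and 9.82 CPM over the wild-type mock libraries. PER1 (7.39, 1.15 and 7.87 CPM) and BGLU19 (8.52, 2.15 and 13 CPM), outside the list, were also lowest in cdk8 ABA replicate 2. Both had been named for being higher in cdk8 after ABA in these same libraries. Induction by ABA in all cdk8 seedlings could not be decided. Of the 3 cdk8 ABA libraries, 2 lay above the highest cdk8 mock library, at 0.63, and 1 did not. That 1 was replicate 2, which at −0.47 lay within the range of the cdk8 mock libraries (−0.93, 0.63 and −0.42). It showed no rise over them, though this rests on 1 library.

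Clock genes moved by phase with ABA and, in part, with genotype. A later time of day at the harvest of the ABA libraries may explain the first, since 11 of 12 clock genes were called in the direction of a later phase in both genotypes. Direct action of ABA on these genes remains open, because the harvest time of the mock libraries is not given in the sources used here. An earlier clock phase at the harvest of the cdk8 mock libraries is a candidate explanation for the second, with 8 of 12 genes called in that direction, the least the test asked for, and 0 in the other. The pattern was not confined to mock libraries. After ABA 3 morning genes were higher and 3 evening genes lower in cdk8, with 0 in the other direction. Action of CDK8 on the clock remains open as well, untested.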

How the results depend on the processing

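Thinning to equal depth, leaving out both ABA libraries that stood apart, leaving out cdk8 ABA replicate 3 for the lists, and the replicate block were chosen after the result was seen. Within 1.5 times the count reported were, at adjusted p under 0.05, the genes changed by ABA in each genotype under every change of scaling, tool, filter, groups in the fit, depth and single library, from 12674 to 13977 in wild type and from 11828 to 13399 in cdk8. Thinned to equal depth, the 5 comparisons gave 13527, 12633, 2716, 4745 and 1078 genes, so the deeper cdk8 ABA libraries did not set these counts. With a 2-fold limit, which by construction lowers counts, 6115, 5480, 794, 1155 and 448 genes remained. At adjusted p under 0.01 the genotype comparisons after mock and after ABA and the difference of responses gave 1129, 2378 and 269, and the overlap of both genotype differences fell to 481 genes from 1244. Fitting only the groups compared gave 4472 genes after mock and 2931 after ABA, which turned the order of the 2781 and 4999 reported. The reported fit shares 1 estimate of the spread over all groups. Between replicates, chi-square per degree of freedom was 6.09 to 9.31 after mock. It was 23.5 to 29.5 in ABA pairs holding a library that stood apart, and 10.9 and 8.77 in the other ABA pairs. Leaving out both ABA libraries that stood apart gave 4383 after mock, with 2780 of the 2781 shared, and 2063 for the difference of responses, with 1022 of 1103 shared. DESeq2 gave 1714 for the difference of responses, with 1091 shared. The cause was not tested. With a replicate block the 5 counts were 13280, 12492, 2201, 4147 and 650, with 645 of the 650 among the 1103. Pairing by replicate number was not established, since only 2 of 18 same-number correlations passed 0.1, with a range of −0.294 to 0.157.

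Leaving out single libraries gave 1486 to 3432 genes after mock, 3099 to 5284 after ABA and 540 to 1493 for the difference of responses. After mock the count moved over 1.5 times without wild-type mock replicates 1 (1761), 2 (1759) or 3 (1608) and cdk8 mock replicates 1 (1782) or 2 (1486), after ABA without cdk8 ABA replicate 1 (3099), and for the difference of responses without wild-type mock replicates 1 (678), 2 (688) or 3 (586), cdk8 mock replicates 1 (540) or 2 (629), or cdk8 ABA replicate 1 (545). Most leave-outs lowered these counts. Counts after mock rose without wild-type ABA replicates 1 (3222) or 3 (3432) or cdk8 ABA replicate 2 (3193), after ABA without cdk8 ABA replicate 2 (5284), and for the difference of responses without wild-type ABA replicate 3 (1493) or cdk8 ABA replicate 2 (1418). The cause was not tested. The median difference in size of the ABA response, cdk8 minus wild type, stayed negative with other gene limits, a prior count of 0.5, RLE scaling, organelle genes left out, thinning, both ABA libraries left out and single libraries left out, −0.152 to −0.08 without single libraries. For falling genes (−0.12, permutation p = 0.035) the call was lost with a 4-fold limit (−0.113, p = 0.06), no fold limit (−0.088, p = 0.075), a prior count of 0.5 (−0.12, p = 0.05), RLE scaling (−0.1, p = 0.06), thinning (−0.108, p = 0.05) and both ABA libraries left out (−0.127, p = 0.05). Without single libraries it ran from −0.146 to −0.077, and the call was lost without wild-type mock replicates 1 (0.115), 2 (0.05) or 3 (0.15), wild-type ABA replicate 1 (0.085) or cdk8 ABA replicate 1 (0.055).

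With an estimated correlation, 5, 6, 0, 0 and 0 lists passed in the 5 comparisons in place of 14, 15, 9, 14 and 5, and the lowest adjusted p were 0.0886, 0.307 and 0.656 where none did. Without cdk8 ABA replicate 3, 2 lists passed for the difference of responses, with PP2C (0.0827), photosynthesis (0.122) and root (0.108) lists lost. With both ABA libraries left out, cell cycle genes (0.0643) and the RAP2.6 group (0.053) were lost after mock, and glucosinolate (0.103) and heat (0.0518) lists after ABA. The same setting added seed genes after mock (0.0163) and for the difference of responses (0.0135), mitochondrial stress genes after ABA (0.027), wax genes for ABA in wild type (0.025) and salicylic acid genes for ABA in cdk8 (0.00508). Without cdk8 ABA replicate 3, wax and auxin lists passed for ABA in wild type (0.0453 for both), and RAP2.6 (0.0528) after mock and glucosinolate (0.0557) and photosynthesis (0.0967) lists after ABA were lost. Of 343 results for named genes, 207 were the same under every alternative and 1 reversed, and of 337 called, 286 were called whichever library was left out. CDK8 reversed in the difference of responses, −0.17 and not called (adjusted p = 0.807), to 0.031 with both ABA libraries left out, 0.105 without cdk8 mock replicate 2 and 0.08 without cdk8 ABA replicate 2, with −0.383 to 0.105 over single libraries. Depth limited genes near the floor, where 3 counts over a group were 0.037 to 0.0565 CPM.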

Other observations

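The iron genes and the search by chromosome position were chosen after the result was seen.

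Of 15 genes known to rise under iron deficiency, picked after values had been seen, 13 were higher in cdk8 after mock and none lower, with a median log2 fold change of 1.92. The count includes 5 genes whose rise prompted the choice, and without them 8 of 10 were higher, with a median of 0.74. Those 8 still include NAS2 and CYP82C4, which had been named for large changes in other comparisons. The set was not tested as a list. FRO2 (4.16), IRT1 (2.90), bHLH38 (3.73), bHLH39 (3.37) and bHLH101 (2.03, adjusted p = 0.00109) were among them, with the nicotianamine synthase genes NAS2 (1.96, adjusted p = 0.001) and NAS4 (0.69, adjusted p = 0.0194). FIT (−0.03, adjusted p = 0.954) and IRT2 (−0.34, adjusted p = 0.392) were not called. The 3 ferritin genes tested were lower, FER1 at −1.76 (207 to 61.2 CPM, adjusted p = 5.74e-05), FER3 at −0.50 (adjusted p = 0.0183) and FER4 at −0.93 (adjusted p = 0.00144).

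ABA lowered most iron deficiency genes in both genotypes. In wild type 12 of 15 fell and 3 rose (median −2.16), and in cdk8 13 fell and none rose (median −3.53). FRO2 fell by 2.16 in wild type and by 5.26 in cdk8, a difference of −3.11 (adjusted p = 0.00608). It went from 2.53 to 0.571 CPM in wild type and from 45.6 to 1.18 CPM in cdk8. After ABA FRO2 was not called different between the genotypes (1.06, adjusted p = 0.0752). FER1 rose by 1.27 in wild type and 2.27 in cdk8. Under ABA 3 of the 15 were higher and 1 lower in cdk8, among them IRT1 at 3.27 (adjusted p = 0.0357). IRT1 then measured 0.0961 CPM in wild type, near the floor, and 0.957 CPM in cdk8, so the size of this difference is uncertain.

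No excess by position was called among genes that differed at least 2-fold between the genotypes, 794 after mock and 1155 after ABA. Of 112 windows of 1 Mb, the only size tried, the lowest adjusted p was 0.692 after mock and 0.338 after ABA.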
